A study of Mus musculus with 23 samples.

How the data were processed

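The libraries came from whole jejunum of mice with fat and Peyer's patches removed, per the labels' protocols. Total RNA was isolated with the PureLink RNA Mini kit and libraries were prepared with an Illumina TruSeq stranded RNA kit, per the labels' protocols. Reads were aligned to the mouse genome (builds named mm10 and GRCm38) with STAR and assigned to genes with featureCounts from Subread 1.5.1, per the submitters' processing notes. The deposited values were raw read counts per Ensembl gene, which were used as deposited. The strand setting of the counting, the version of STAR and the annotation release were not given in the sources used here. Reads of a gene and of an overlapping antisense gene can therefore not be told apart, and genes with near-identical copies, such as the mast cell protease and defensin families, can share reads.

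The count table held 55487 genes in 23 libraries, of which 55141 were given a symbol, chromosome and position from GENCODE vM21 on GRCm38 by their Ensembl identifier. The 346 genes without a symbol held 0.0305% of the reads and kept their identifier. Total counts per library ran, in M (mega), from 5.48 to 19.34 with a median of 13.81. Genes with low counts were removed with edgeR's filterByExpr by group, which left 17236 genes. Libraries were scaled with TMM factors, and CPM values were computed with these factors. Group values are given as mean CPM ± SD with n libraries.

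Each library was placed in 1 of 10 groups of genotype and state from its title, treatment and time labels. Differences were tested with edgeR 4.0.16 (robust quasi-likelihood fit and F test) in R 4.3.3, in 1 model of 10 group means with sex as a covariate. The model left 12 residual degrees of freedom, and a biological coefficient of variation of 28.6%. Most groups held 2 libraries, so the spread was estimated over all groups. The labels did not say that the libraries of a group came from separate animals. The Cpa3+/+ naive and the Cpa3Cre/+ naive, immunized, day 1 and day 3 groups held both sexes. Their male and female libraries therefore came from different animals. P-values measure the spread between these libraries, which may be technical among libraries of the same sex in a group. The comparisons were Cpa3Cre/+ against Cpa3+/+ averaged over the 5 states and in each state, immunized against naive and each challenge day against immunized within each genotype, and the difference of the challenge responses between genotypes on each day and over the 3 days jointly. Tests were two-sided and p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Counts of genes at an unadjusted p under 0.05 are given as values only. Evenly spread p-values would put a share of 0.05 of the tested genes there, and several counts lie below that share. Log2 fold changes are given with a standard error. For edgeR this was computed as the absolute log2 fold change over the square root of its F statistic. It is approximate, above all where a group held few counts. The labels named no test, so this design was chosen before the data were examined.

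In addition, 44 gene lists of cell types and pathways were fixed before the data were examined. For each list, members were counted whose p passed 0.05 when adjusted over the list alone, beside the count over all genes; a member is described as risen or fallen when it passed either. Counts over a list alone were not corrected across lists. Each list was also tested against all other genes with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and again with the correlation estimated, and with fry, which asks whether the members move on balance in 1 direction. These p-values were adjusted over the 44 lists within a comparison.

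Named genes followed a rule fixed before the data were examined. Cpa3, Mcpt1, Mcpt2, Kit and Fcer1a were always given. Per comparison the rule took the 5 largest changes in each direction among called genes with at least 1 CPM in a compared group, or 10 for the genotype average, without predicted genes, antigen receptor segments, Y-linked genes and Xist. Per list it took at most 4 members passing with the smallest p, and up to 2 members given as values where none passed. Cpa3, Fcer1a, St3gal4, Pla2g4c and the gasdermin genes within single states or responses, the called pseudogene Gm10060, the genes called by DESeq2 alone, and the genes given as values per library were chosen after their values were seen. Some genes that the rule would name are not reported here; they stay in the counts. Where all libraries of a group held 0 counts, a fold was computed against a floor of 3 counts over the group and is a lower bound that covers counting error only.

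The alternatives fixed before the data were examined were DESeq2 size factors in the same edgeR test, no filter on low counts, DESeq2 1.42.0 in place of edgeR, no sex covariate, female libraries only, the replicate number as a block, and each library left out in turn. Further alternatives were chosen after the data were seen: a correction of each library for the GC content of transcripts, the omission of 3 libraries apart on the first principal components, the omission of 3 libraries with B cell follicle transcripts, and an enterocyte score as a covariate for the sugar list. GC values covered 99.9% of the genes tested. The edgeR fit was tested on simulated counts of 16675 genes with 50 genes changed 2-fold and 50 changed 4-fold in a comparison. The changed genes had over 1 CPM, and genes were drawn independently, without outlying libraries or GC slopes. For the genotype average it recovered 76% of the 2-fold and 96% of the 4-fold changes and called 9 unchanged genes. For day 5 against immunized in Cpa3+/+ it recovered 2% and 62%, and called 2 unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.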

Results

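Gene expression was measured by RNA sequencing in whole jejunum of Cpa3+/+ (wild type) and Cpa3Cre/+ mice, which the labels describe as mast cell-deficient. The 23 libraries comprised 12 from Cpa3+/+ and 11 from Cpa3Cre/+ mice. Mice were naive, immunized, or immunized and challenged. Immunization was 25 µg ovalbumin with 2 mg alum intraperitoneally on days 0 and 14. Challenged mice had a choice between water and water with 20% egg white and 8% sugar from day 20 on, for 1, 3 or 5 days. The amounts drunk were not given. Cpa3+/+ mice contributed 3 naive, 2 immunized, 3 day 1, 2 day 3 and 2 day 5 libraries, and Cpa3Cre/+ mice contributed 2, 2, 2, 2 and 3. Of the libraries, 18 came from females. The 5 males were Cpa3+/+ naive replicate 3 and 1 library each of the naive, immunized, day 1 and day 3 Cpa3Cre/+ groups. Total counts of the Cpa3+/+ libraries, in M (mega), were 5.48, 9.67 and 14.54 (naive), 13.81 and 11.91 (immunized), 14.3, 12.77 and 13.96 (day 1), 14 and 13.97 (day 3), and 10.94 and 13.32 (day 5). Those of the Cpa3Cre/+ libraries were 7.55 and 11.08 (naive), 14.97 and 14.35 (immunized), 16.14 and 12.13 (day 1), 14.25 and 19.34 (day 3), and 13.25, 12.34 and 13.86 (day 5).

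The genotype comparison asked which jejunal transcripts differ in mice described as lacking mast cells. The targeted gene was read first. Cpa3 (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181, minus strand, GRCm38) encodes carboxypeptidase A3, a protease stored in mast cell granules. In Cpa3+/+ jejunum it averaged 1.21 ± 0.547 CPM in naive mice (SD, n = 3), 3.23 ± 1.16 after immunization (n = 2), 4.67 ± 2.48 on day 1 (n = 3), 15.2 ± 2.93 on day 3 (n = 2) and 13.1 ± 12.8 on day 5 (n = 2). In Cpa3Cre/+ jejunum the means were 0.587 ± 0.687 (n = 2), 0.222 ± 0.0979 (n = 2), 0.42 ± 0.283 (n = 2), 0.834 ± 0.194 (n = 2) and 1.45 ± 0.0969 (n = 3). In the immunized and challenged states every Cpa3Cre/+ library lay below every Cpa3+/+ library of its state. In the naive state the library labelled Cpa3Cre/+ naive replicate 1 had 1.07 CPM, inside the naive Cpa3+/+ range of 0.827 to 1.84 CPM, so the targeted gene did not check that label.

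Averaged over the 5 states, 5 of 17236 genes tested were lower in Cpa3Cre/+ jejunum and 0 were higher, and all 5 are mast cell genes by textbook knowledge. Cpa3 fell by 3.05 on the log2 scale (−3.05 ± 0.40 SE, 8.3-fold, edgeR adjusted p = 0.0102). The mucosal mast cell chymases Mcpt1 (ENSMUSG00000022227, chromosome 14, 56017971 to 56020384) and Mcpt2 (ENSMUSG00000022226, chromosome 14, 56042041 to 56044642) changed by −2.31 ± 0.35 and −2.30 ± 0.38 (edgeR adjusted p = 0.0283 and 0.0369). The related protease Mcpt9 (ENSMUSG00000071361, chromosome 14, 56026864 to 56030495) changed by −2.83 ± 0.45, and Fcer1a (ENSMUSG00000005339, chromosome 1, 173221284 to 173227214), the alpha chain of the high-affinity IgE receptor, by −2.89 ± 0.45 (edgeR adjusted p = 0.0342 and 0.0283). Both averages include immunized Cpa3Cre/+ mice, where Mcpt9 (0 and 0.153 CPM) and Fcer1a (0 and 0.0764 CPM) had too few counts for a fold. The size of these 2 averages is therefore uncertain. The transcript of Kit, a receptor tyrosine kinase found on mast cells and on interstitial cells of Cajal, had a log2 fold change of −0.15 ± 0.20 (edgeR adjusted p = 1).

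The mast cell lists moved with these genes. Of 8 measured mast cell proteases, 7 fell adjusted over the list alone and 3 over all genes; Mcpt4, a connective tissue mast cell chymase, changed by −2.42 ± 0.46. The list median was −2.30, and the list was lower by camera (adjusted p = 2.98e-24), also with an estimated correlation (adjusted p = 0.00615), and by fry (adjusted p = 0.0279). Of 15 other mast cell markers, 3 fell adjusted over the list alone and 1 over all genes: Fcer1a, Ms4a2, the beta chain of the IgE receptor (−2.50 ± 0.50), and Tph1, an enzyme of serotonin synthesis that enterochromaffin cells express as well (−0.67 ± 0.23). The camera call of that list (adjusted p = 2.58e-05) was lost (adjusted p = 0.24 with an estimated correlation). Ms4a2 was also the only 1 of 3 basophil genes that fell (adjusted p = 0.24 with an estimated correlation for that list). The averages of Mcpt4 and Ms4a2 are uncertain in size as well. In immunized Cpa3Cre/+ mice they stood at 0 and 0.153 CPM and at 0.0728 and 0 CPM. Of the protease list, Mcpt1, Mcpt2, Mcpt4, Mcpt9, Cma1 and Cma2 lie close together on chromosome 14 and resemble each other, so their reads can be shared.

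The count of 5 depended on single libraries. It was 0 without Cpa3+/+ naive replicate 3, Cpa3Cre/+ immunized replicate 2, day 1 replicate 1 or day 3 replicate 1. It was 1 without Cpa3+/+ naive replicate 1 or 2, immunized replicate 2, day 3 replicate 1 or 2, the library labelled Cpa3Cre/+ naive replicate 1, or Cpa3Cre/+ immunized replicate 1, day 3 replicate 2 or day 5 replicate 1 or 3, and 3 without Cpa3+/+ day 1 replicate 1. Wherever the count was 1, the gene called was Cpa3, the targeted gene, and no other mast cell gene passed. In these 23 fits the log2 fold changes of the 5 genes ranged from −3.69 to −1.92. DESeq2 called 8 genes, which included the 5. With the female libraries alone 0 genes were called, and the 5 genes had log2 fold changes of −2.86 to −2.16. The count was also 0 without the 3 libraries apart on the principal components (log2 fold changes of −3.64 to −2.63) and without the 3 libraries with follicle transcripts (−3.57 to −2.56), both chosen after the data were seen.

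**Figure D1:**
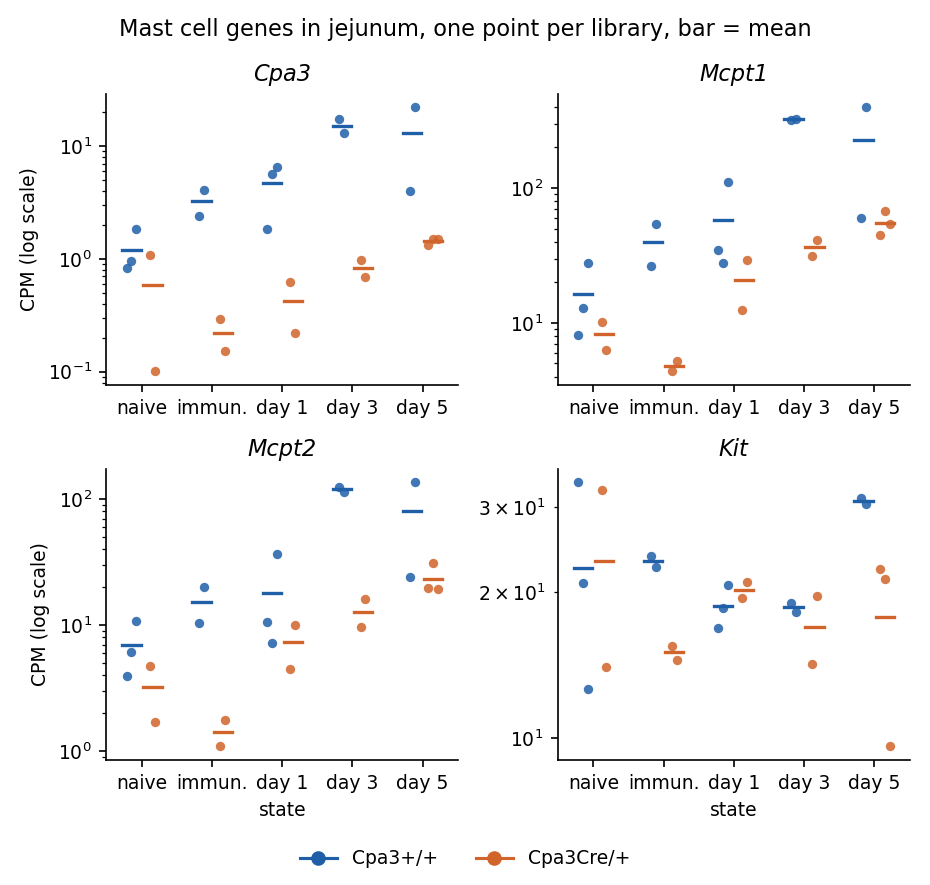
Normalised expression of Cpa3, Mcpt1, Mcpt2 and Kit (CPM, log axis) in each library by state, with Cpa3+/+ in blue and Cpa3Cre/+ in orange; bars are group means. Mcpt1 reached 323 CPM on day 3 in Cpa3+/+ and 36.2 CPM in Cpa3Cre/+ jejunum, while Kit lay between group means of 15 and 30.9 CPM.

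Within single states, mast cell genes separated the genotypes most after immunization and on day 3. Mcpt1 averaged 40.1 ± 19.2 CPM in immunized Cpa3+/+ and 4.78 ± 0.583 CPM in immunized Cpa3Cre/+ jejunum (n = 2 each; log2 fold change −3.31 ± 0.81), and 323 ± 6.08 against 36.2 ± 6.83 CPM on day 3 (n = 2 each; −3.44 ± 0.79). Adjusted over the list alone, 7 of 8 mast cell proteases were lower in immunized mice, 7 of 8 on day 3, 4 of 8 on day 5 and 0 in naive mice and on day 1. With an estimated correlation the camera call of the mast cell proteases held in immunized mice (adjusted p = 0.0387) and on day 3 (adjusted p = 0.00458) and was lost on day 5 (adjusted p = 0.492). On day 5 the fallen members were Mcpt1 (−2.04 ± 0.63), Mcpt2 (−1.78 ± 0.65), Mcpt4 (−1.87 ± 0.70) and Mcpt9 (−3.31 ± 0.70). In Cpa3+/+ day 5 replicate 1, Mcpt1, Mcpt2 and Mcpt4 (59.6, 24 and 2.01 CPM) lay inside the range of the Cpa3Cre/+ day 5 libraries. Mcpt9 (3.46 CPM) lay above that range. Replicate 2 stood above the range in all of them, at 397, 137, 12.4 and 18.6 CPM. Of 15 other mast cell markers, 2 were lower in immunized mice (Fcer1a and Ms4a2). On day 3 there were 4, and on day 5 there were 3 with Slc18a2, a vesicular monoamine transporter, at −2.14 ± 0.58. The camera calls of the other markers were lost with an estimated correlation in immunized mice (adjusted p = 0.472) and on day 3 (adjusted p = 0.24). In immunized Cpa3Cre/+ mice Fcer1a averaged 0.0382 ± 0.054 CPM and Mcpt9 0.0764 ± 0.108 CPM (n = 2), too few counts for a fold.

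Over all genes edgeR called 0 genes in each state, with 921, 164, 1274, 267 and 1596 genes at an unadjusted p under 0.05 in naive, immunized, day 1, day 3 and day 5 mice. Evenly spread p-values would put a share of 0.05 of the 17236 genes there, and the 164 and 267 lie below that share. DESeq2 called 0, 0, 3, 7 and 15. Its 7 genes on day 3 were Cpa3, Mcpt1, Mcpt2, Mcpt4, Mcpt9, Fcer1a and ENSMUSG00000095742, all lower in Cpa3Cre/+. Without the library labelled Cpa3Cre/+ naive replicate 1 edgeR called 1 gene in naive mice, and on day 5 it called 1 without that library, without Cpa3Cre/+ naive replicate 2 and without Cpa3Cre/+ day 5 replicate 3. The protease counts were 3 in immunized mice without Cpa3Cre/+ immunized replicate 1, and on day 5 they were 0 without Cpa3+/+ day 5 replicate 2 and 1 without Cpa3Cre/+ day 5 replicate 1. The counts of other markers were 2, 0 and 1 on day 3 without Cpa3+/+ day 3 replicate 2 and Cpa3Cre/+ day 3 replicates 1 and 2, and 1 and 0 on day 5 without Cpa3+/+ day 5 replicate 2 and Cpa3Cre/+ day 5 replicate 3. In immunized mice they were 0 without Cpa3+/+ immunized replicate 2 or Cpa3Cre/+ immunized replicate 1 and 1 without Cpa3Cre/+ immunized replicate 2.

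Naive and day 1 jejunum gave few list members that passed between genotypes, and mast cell genes were not among them. In naive mice the Paneth cell defensins Defa22 and Defa26 were higher in Cpa3Cre/+, 2 of 14 members adjusted over the list alone and 0 over all genes. Defa22 stood at 71.5 CPM in Cpa3Cre/+ naive replicate 2 and at 0.724 CPM or less in every other library, and Defa26 at 37.9 CPM against 9.29 CPM or less. The count was 0 without that library, Cpa3+/+ naive replicate 3 or Cpa3Cre/+ immunized replicate 1 or 2. On day 1 the members that passed were Iglc3, an immunoglobulin light chain gene (2.18 ± 0.60), S1pr2, a receptor of germinal centre B cells (1.62 ± 0.49), the clock repressors Cry1 (−1 ± 0.30) and Cry2 (−1.91 ± 0.57), the gluconeogenic enzyme Pck1 (−3 ± 0.97) and the p53 target Pmaip1 (−2.64 ± 0.73), in each list 1 or 2 members and 0 over all genes. The plasma cell and clock lists lost their camera calls (adjusted p = 0.578 for both with an estimated correlation). Cpa3+/+ day 1 replicate 2 carried the last 3 of these differences: Pck1 stood there at 7483 CPM, Cry2 at 123 CPM and Pmaip1 at 736 CPM, against at most 884, 28.2 and 99 CPM in every other library. Without it the counts of the clock, fat cell (Pck1), p53, germinal centre and plasma cell lists were all 0. The clock count was also 0 without either Cpa3Cre/+ day 1 library, and the p53 count without either of these, Cpa3+/+ naive replicate 3, Cpa3Cre/+ immunized replicate 1 or 2 or day 5 replicate 3. The germinal centre count was also 0 without Cpa3+/+ naive replicate 3, day 1 replicate 1 or 3 or Cpa3Cre/+ day 1 replicate 2. The fat cell and plasma cell counts were 0 without 14 of the 23 libraries each, among them Cpa3Cre/+ day 1 replicate 2.

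On day 5, some genes of sugar handling, of the cell cycle and of Paneth cells passed between the genotypes, and all 3 lists lost their camera calls with an estimated correlation (adjusted p = 0.492, 0.459 and 0.492). Of 14 genes of sugar uptake and fructose metabolism, 7 were higher in Cpa3Cre/+ adjusted over the list alone and 0 over all genes, with a list median of 1.09. The fructose transporter Slc2a5 (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169) averaged 86.3 ± 36.7 CPM in Cpa3+/+ (n = 2) and 310 ± 70.3 CPM in Cpa3Cre/+ (n = 3; 1.84 ± 0.47), against 155 ± 13.6 and 282 ± 65.8 CPM in the immunized mice of the same genotypes. The fructose-metabolising enzymes Khk (1.51 ± 0.45), Tkfc (1.23 ± 0.38) and Fbp1 (1.40 ± 0.46) were higher as well. All 19 absorptive enterocyte genes had positive log2 fold changes with a median of 0.76, and 0 of them passed adjusted over the list alone (adjusted p = 0.492 with an estimated correlation).

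Of 20 proliferation genes, 10 were lower in Cpa3Cre/+ on day 5 adjusted over the list alone and 0 over all genes, with a list median of −0.53 (adjusted p = 0.459 with an estimated correlation). Cyclin A2 (Ccna2, ENSMUSG00000027715) changed by −0.73 ± 0.18, cyclin B1 (Ccnb1) by −0.69 ± 0.20 and the mitotic motors Kif11 and Cenpe by −0.80 ± 0.25 and −0.88 ± 0.28. Of 14 Paneth cell genes, 3 were lower: lysozyme (Lyz1, −1.48 ± 0.51), the defensin Defa5 (−1.69 ± 0.52) and Nupr1 (−1.28 ± 0.38). That list lost its camera call (adjusted p = 0.492 with an estimated correlation), and its count was 0 without either Cpa3+/+ day 5 library or without Cpa3Cre/+ day 5 replicate 2 or 3. Of 28 interferon response genes, 3 were higher, Ifit3 (1.59 ± 0.46), Igtp (1.53 ± 0.46) and Usp18 (1.87 ± 0.58), and 22 had positive values (adjusted p = 0.492 with an estimated correlation). The epithelial alarm gene Sprr2a1 was the only 1 of 15 that passed, at 1.02 ± 0.559 CPM (n = 3) against 0.0668 ± 0.0945 CPM in Cpa3+/+ (n = 2; adjusted p = 0.492 with an estimated correlation for that list). Iglc3 changed by −2.87 ± 0.53, the only 1 of 20 plasma cell and immunoglobulin genes that passed; it had 96.2 ± 26.2 CPM in Cpa3+/+ day 5 (n = 2) and between 9.77 and 41.3 CPM in the other 9 groups (adjusted p = 0.644 with an estimated correlation for that list). The sialyltransferase St3gal4 stood at 135, 142 and 73.2 CPM in the 3 Cpa3Cre/+ day 5 libraries and at most 32.4 CPM in any other library (3.1 ± 0.58, edgeR adjusted p = 0.365, DESeq2 adjusted p = 0.00011).

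The calls between the genotypes on day 5 depended on the libraries left out. The Sprr2a1 call was lost without Cpa3+/+ day 5 replicate 1 or Cpa3Cre/+ day 5 replicate 2, and the Iglc3 call held without any 1 library. The sugar count was 0 without Cpa3+/+ day 5 replicate 1, 3 without replicate 2, and 4, 4 and 1 without Cpa3Cre/+ day 5 replicates 1, 2 and 3. The proliferation count was 0 without Cpa3+/+ day 5 replicate 1 or Cpa3Cre/+ day 5 replicate 1, 6 without Cpa3+/+ day 5 replicate 2 and 2 without Cpa3Cre/+ day 5 replicate 3. The interferon count was 0 without Cpa3+/+ naive replicate 2, immunized replicate 1 or 2, day 1 replicate 3, day 3 replicate 1 or 2 or day 5 replicate 1 or 2, or without Cpa3Cre/+ day 5 replicate 1 or 3.

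**Figure D2:**
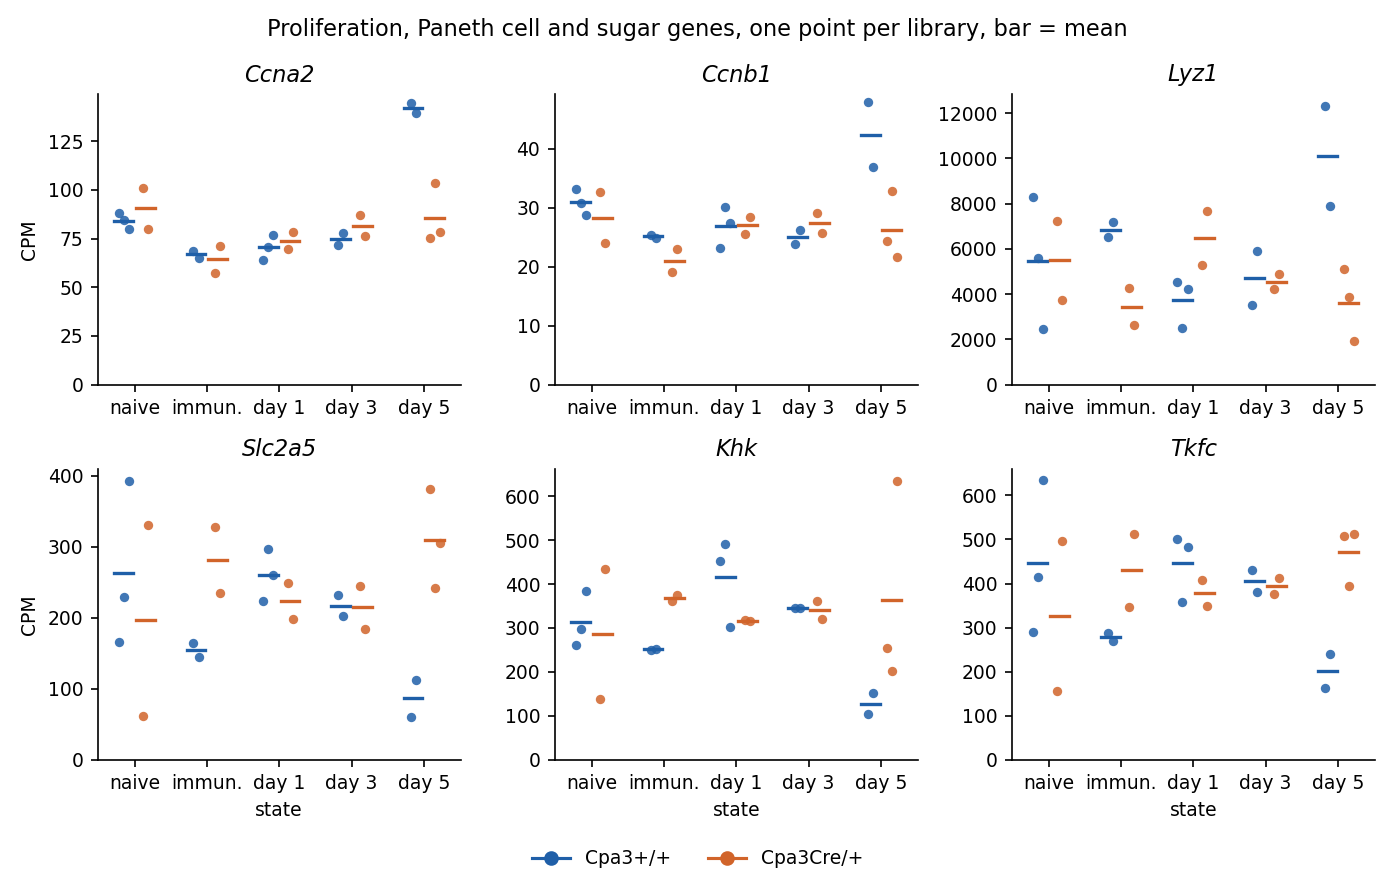
Normalised expression (CPM) of the proliferation genes Ccna2 and Ccnb1, the Paneth cell gene Lyz1 and the sugar genes Slc2a5, Khk and Tkfc in each library by state, with Cpa3+/+ in blue and Cpa3Cre/+ in orange; bars are group means. On day 5 Ccna2 averaged 142 CPM in Cpa3+/+ and 85.8 CPM in Cpa3Cre/+, and Slc2a5 averaged 86.3 and 310 CPM.

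The comparison of immunized with naive mice asked what immunization alone changed in the jejunum. In Cpa3+/+ mice, clock genes moved: of 17, 8 passed adjusted over the list alone, 6 lower and 2 higher, and 0 over all genes. The camera call of that list (adjusted p = 5.74e-06) was lost (adjusted p = 0.243 with an estimated correlation). Hlf, a clock output factor, went from 25.5 ± 5.01 CPM (n = 3) to 5.73 ± 2.34 CPM (n = 2; −2.19 ± 0.50), with Per2 at −1.70 ± 0.52, Per3 at −1.85 ± 0.58 and Bhlhe40 at −0.85 ± 0.25. Bco1, a carotenoid-cleaving enzyme of the proximal intestine, changed by −2.87 ± 0.85 as the only 1 of 11 proximal genes that passed, and did not pass without Cpa3+/+ naive replicate 2, immunized replicate 1 or 2, day 1 replicate 2 or day 5 replicate 1 or 2. The times of day of sampling were not given in the labels. Over all genes edgeR called 0, with 292 at an unadjusted p under 0.05, and DESeq2 called 4, among them Hlf (adjusted p = 0.0371) and the complement gene C3 (2.48 ± 0.56 by DESeq2, adjusted p = 0.0371). The clock count was 1 without Cpa3+/+ naive replicate 2, and 0 and 3 without Cpa3+/+ immunized replicates 1 and 2. It was 5 without Cpa3+/+ day 3 replicate 1 or 2 or day 5 replicate 1 or 2, without the library labelled Cpa3Cre/+ naive replicate 1, or without Cpa3Cre/+ naive replicate 2, day 1 replicate 1 or 2, day 3 replicate 1 or 2, or day 5 replicate 1 or 3.

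In Cpa3Cre/+ mice, muscle and nerve genes were lower in immunized than in naive jejunum, a difference that rested on 1 library of each group. The camera calls of the smooth muscle, neuron and glia lists were lost with an estimated correlation (adjusted p = 0.442, 0.442 and 0.505). Of 12 smooth muscle genes 10 fell adjusted over the list alone, of 16 enteric neuron genes 9 and of 10 enteric glia genes 4, and 0 over all genes. The muscle genes Tagln (−2.13 ± 0.63), Myh11 (−1.96 ± 0.60) and the neuropeptide Vip (−1.91 ± 0.44) were among them. The integrin of intraepithelial lymphocytes Itgae (1.55 ± 0.36) and the T cell receptor subunit Cd3e (2.09 ± 0.61) rose, 2 of 23 T cell genes, as did Mzb1 (3.00 ± 0.69) and Ighg2b (2.58 ± 0.77), 2 of 20 plasma cell genes (adjusted p = 0.442 for both lists with an estimated correlation). Cd3e stood at 1.27 CPM in the library labelled Cpa3Cre/+ naive replicate 1 and at 5.23 CPM in replicate 2. The T cell count was 0 without the former or without Cpa3Cre/+ immunized replicate 2, and 1 without any 1 of the Cpa3+/+ naive and day 3 or Cpa3Cre/+ day 3 libraries. The plasma cell count was 0 without Cpa3Cre/+ naive replicate 2 or immunized replicate 1. Of 13 mitochondrially encoded genes 5 fell, with mt-Co3 at −1.41 ± 0.38 (adjusted p = 0.505 with an estimated correlation). The library labelled Cpa3Cre/+ naive replicate 1 had the highest Myh11 of all libraries, 1640 CPM. Each absorptive enterocyte gene was lower in that library than in naive replicate 2 and both immunized Cpa3Cre/+ libraries. Anpep stood at 1652 CPM there, at 9573 CPM in naive replicate 2 and at 9446 and 10150 CPM after immunization. Fabp2 stood at 1227, 6569, and 6675 and 4960 CPM. Of the enterocyte genes 0 passed adjusted over the list alone. The share of epithelium and muscle in that sample was not tested.

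Smaller lists moved in that comparison as well. The immediate early genes Klf4 (1.81 ± 0.56), Jun (1.06 ± 0.34) and Zfp36 (1.30 ± 0.42) rose, 3 of 19 adjusted over the list alone and 0 over all genes (adjusted p = 0.442 with an estimated correlation). Gjc1 (−1.43 ± 0.51), Etv1 (−1.71 ± 0.63) and Prkcq (−1.51 ± 0.61) fell, 3 of 6 genes of interstitial cells of Cajal, the pacemaker cells of the gut wall (adjusted p = 0.505 with an estimated correlation). Prkcq stood at 17.8 CPM in the library labelled Cpa3Cre/+ naive replicate 1 and at 2.42 CPM in replicate 2, below the 2.99 and 3.06 CPM of the immunized libraries, and it turned to 0.25 without the 3 libraries apart on the principal components. The fat cell genes Fabp4 (−1.75 ± 0.53) and Plin4 (−2.23 ± 0.76) fell, 2 of 7, as did the globin Hbb-bt (−3.14 ± 1.08), 1 of 5 blood genes (adjusted p = 0.505 with an estimated correlation). Defa26 (−3.37 ± 0.82) and Defa22 fell, 2 of 14 Paneth cell genes, from 37.9 and 71.5 CPM in Cpa3Cre/+ naive replicate 2 (adjusted p = 0.532 with an estimated correlation). In the library labelled Cpa3Cre/+ naive replicate 1 they were 4.88 and 0.0975 CPM, and in the immunized libraries 1.89 and 1.76 CPM and 0.0728 and 0.0764 CPM. The chymase Cma1 went from 0.44 ± 0.48 CPM to 0 counts (n = 2 each), 1 of 8 mast cell proteases. The Paneth cell count was 0 without Cpa3Cre/+ naive replicate 2 or immunized replicate 1. The protease count was 0 without the library labelled Cpa3Cre/+ naive replicate 1 or either Cpa3Cre/+ immunized library. The fat cell count was 0 without the library labelled Cpa3Cre/+ naive replicate 1 or Cpa3Cre/+ immunized replicate 2 and 1 without Cpa3Cre/+ day 3 replicate 1 or 2, and the blood count was 0 without 17 of the 23 libraries. The immediate early count was 0 without any 1 of the 3 Cpa3+/+ naive libraries, Cpa3+/+ day 1 replicate 1, day 3 replicate 1 or 2, or the library labelled Cpa3Cre/+ naive replicate 1. It was 1 without Cpa3Cre/+ immunized replicate 1 or 2. The Cajal cell count was 0 without Cpa3+/+ naive replicate 2 or 3, any 1 of the immunized and challenged Cpa3+/+ libraries, the library labelled Cpa3Cre/+ naive replicate 1, Cpa3Cre/+ immunized replicate 2, day 1 replicate 1 or 2 or day 3 replicate 1 or 2.

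EdgeR called 0 genes over all genes in the comparison of immunized with naive Cpa3Cre/+ mice, with 2265 at an unadjusted p under 0.05, and DESeq2 called 99. The edgeR count was 2000 without Cpa3Cre/+ naive replicate 2, 3 without immunized replicate 2, 1 without the library labelled Cpa3Cre/+ naive replicate 1 and 1 without Cpa3Cre/+ day 5 replicate 3. In the first of these fits the library labelled Cpa3Cre/+ naive replicate 1 stood alone for its group. The muscle, neuron and glia counts were all 0 without the library labelled Cpa3Cre/+ naive replicate 1 or without Cpa3Cre/+ immunized replicate 2, and the mitochondrial count was 3 without the former and 0 without naive replicate 2 or immunized replicate 1 or 2.

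The challenge comparisons asked how the jejunum of immunized mice changed while egg white was offered. In Cpa3+/+ mice on day 1, clock genes rose and B cell genes fell against immunized mice, and both lists lost their camera calls (adjusted p = 0.504 and 0.912 with an estimated correlation). Of 17 clock genes 9 rose adjusted over the list alone and 0 over all genes: Hlf by 2.04 ± 0.49, Per2 by 2.00 ± 0.52, Bhlhe40 by 1.03 ± 0.25 and Ciart by 4.98 ± 1.31, with Ciart at 20.7 ± 29.7 CPM (n = 3) from 0.653 ± 0.338 CPM (n = 2). Of 15 B cell and follicle genes 12 fell, with the transcription factor Pax5 at −4.84 ± 1.53, the complement receptor Cr2 at −4.50 ± 1.44 and Cd79b at −2.49 ± 0.75. Of the libraries compared, Pax5 and Cr2 were high only in Cpa3+/+ immunized replicate 1, at 14 and 19.8 CPM. In immunized replicate 2 they were 0.405 and 0.0811 CPM, and on day 1 they ran from 0.186 to 0.308 and from 0.152 to 0.769 CPM. Without the 3 libraries with follicle transcripts Cr2 turned to 2.28. Germinal centre genes fell too, 3 of 8, among them Gcsam (−2.34 ± 0.83) and S1pr2 (−1.21 ± 0.45; adjusted p = 0.912 with an estimated correlation for that list). Iglc3 fell by 2.08 (−2.08 ± 0.53, 1 of 20 plasma cell genes, adjusted p = 0.912 with an estimated correlation), Irf9 rose (0.79 ± 0.21, 1 of 28 interferon genes), and Herpud1 (2.44 ± 0.67) and Ddit4 (3.05 ± 0.88) rose, 2 of 18 stress response genes. Both stood out in Cpa3+/+ day 1 replicate 2. Herpud1 was 1137 CPM there, 159 and 162 CPM in the other day 1 libraries and 93.5 and 85.1 CPM in the immunized libraries, and Ddit4 was 341, 20.8 and 25.3, and 12.9 and 18.2 CPM. The stress count was 0 without that library, either Cpa3+/+ immunized library or Cpa3Cre/+ day 5 replicate 3. The Iglc3 call was lost without Cpa3+/+ immunized replicate 1 or any 1 of the day 1 libraries, and the Irf9 call without 16 of the 23 libraries.

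EdgeR called 0 over all genes on day 1, with 925 at an unadjusted p under 0.05, and DESeq2 called 19, among them Hlf, Ciart and the glucocorticoid-responsive genes Fkbp5 (4.65 ± 0.98 by DESeq2, adjusted p = 0.0107) and Zbtb16 (5.04 ± 1.19 by DESeq2, adjusted p = 0.042), both highest in Cpa3+/+ day 1 replicate 2. The clock count was 0 without Cpa3+/+ immunized replicate 1 and 3 without Cpa3+/+ day 1 replicate 2. The B cell count was 0 without Cpa3+/+ immunized replicate 1 or day 1 replicate 2 or 3. The germinal centre count was 0 without any 1 of the Cpa3+/+ naive, day 1, day 3 or day 5 libraries, Cpa3+/+ immunized replicate 1, Cpa3Cre/+ immunized replicates 1 and 2, day 3 replicates 1 and 2 or day 5 replicate 2.

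On day 3 the mast cell proteases rose in Cpa3+/+ mice, and the camera call of the list (adjusted p = 8.4e-10) was lost (adjusted p = 0.185 with an estimated correlation). Of 8 members, 5 rose adjusted over the list alone and 0 over all genes: Mcpt1 from 40.1 ± 19.2 to 323 ± 6.08 CPM (n = 2 each; 3.01 ± 0.75, 8.07-fold), Mcpt2 by 2.97 ± 0.78, Mcpt4 by 2.92 ± 0.83 and the chymase Cma1 by 2.46 ± 0.78. Cpa3 had a log2 fold change of 2.23 ± 0.73. Of 13 mitochondrially encoded genes 3 rose, mt-Co3 (1.22 ± 0.38), mt-Co2 (1.26 ± 0.41) and mt-Nd3 (1.23 ± 0.42). Mitochondrially encoded reads made up 6.06 and 5.39% of the day 3 libraries, against 6.73 and 4.87% of the immunized libraries. EdgeR called 0 over all genes, with 849 at an unadjusted p under 0.05, and DESeq2 called 2, the immunoglobulin segments Ighv8-8 and Ighv8-11, both lower. The protease count was 0 without Cpa3+/+ immunized replicate 1, and the mitochondrial count was 0 without either immunized or either day 3 Cpa3+/+ library.

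On day 5 in Cpa3+/+ mice, cell cycle genes rose. The proliferation list passed fry (adjusted p = 0.0154), and its camera call (adjusted p = 2.79e-13) was lost (adjusted p = 0.162 with an estimated correlation). Of 20 proliferation genes 12 rose adjusted over the list alone and 0 over all genes, all 20 had positive values, and the list median was 0.75. Ccna2 went from 66.9 ± 2.6 to 142 ± 3.91 CPM (n = 2 each; 1.09 ± 0.20, edgeR adjusted p = 0.0993, DESeq2 adjusted p = 0.000344), with Ccnb2 at 0.95 ± 0.23, the survivin gene Birc5 at 0.94 ± 0.26 and Ccnb1 at 0.75 ± 0.22. Of 8 mast cell proteases 4 rose: Mcpt1 (2.51 ± 0.74), Mcpt2 (2.40 ± 0.76), Mcpt4 (2.36 ± 0.82) and Mcpt9 (1.86 ± 0.74; adjusted p = 0.926 with an estimated correlation for that list). Mcpt1 stood at 59.6 and 397 CPM in day 5 replicates 1 and 2, against 26.5 and 53.7 CPM in the immunized libraries. Junb, an immediate early factor (−3.41 ± 0.86), and Nr1d1, a clock repressor (−1.75 ± 0.42), fell, 1 of 19 and 1 of 17 members of their lists (adjusted p = 0.926 for both with an estimated correlation). The Junb call was lost without Cpa3+/+ immunized replicate 2 or either day 5 library, and the Nr1d1 call without immunized replicate 1 or day 5 replicate 1. In the same comparison all 19 absorptive enterocyte genes had negative values (median −0.57) and 11 of 13 intestinal stem cell genes had positive values (median 0.69). In both lists 0 members passed, and their camera calls were lost with an estimated correlation (adjusted p = 0.926 for both).

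Over all genes edgeR called 0 on day 5 in Cpa3+/+, with 1602 at an unadjusted p under 0.05, and DESeq2 called 138, 45 higher and 93 lower. The edgeR count was 53 without Cpa3Cre/+ day 5 replicate 3, 9 without the library labelled Cpa3Cre/+ naive replicate 1 and 4 without Cpa3+/+ naive replicate 3, none of them a library of the groups compared. The proliferation count was 2 without Cpa3+/+ immunized replicate 1 and 7 without Cpa3+/+ day 5 replicate 1. The protease count was 0 without Cpa3+/+ immunized replicate 1 or day 5 replicate 2 and 2 without immunized replicate 2.

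In Cpa3Cre/+ mice on day 1, blood genes rose: all 5 measured members passed adjusted over the list alone and 0 over all genes, with the beta globin Hbb-bs going from 15 ± 6.62 to 71.5 ± 18.9 CPM (n = 2 each; 2.29 ± 0.81). The blood list lost its camera call (adjusted p = 0.462 with an estimated correlation). On day 3, 8 of 12 smooth muscle genes rose (adjusted p = 0.444 with an estimated correlation), with Actg2 at 2.35 ± 0.71, Tagln at 1.87 ± 0.61, Des at 1.95 ± 0.67 and Acta2 at 1.57 ± 0.59. Mcpt1 went from 4.78 ± 0.583 to 36.2 ± 6.83 CPM (n = 2 each; 2.88 ± 0.78) and Mcpt2 changed by 3.11 ± 0.88, 2 of 8 mast cell proteases. Itgae fell (−1.27 ± 0.35, 1 of 23 T cell genes), and the protease and T cell lists lost their camera calls (adjusted p = 0.444 for both with an estimated correlation). The neutrophil genes S100a8 and S100a9 averaged 2.83 ± 3.65 and 4.54 ± 5.65 CPM on day 3, against 0.0728 ± 0.103 and 0.149 ± 0.00505 CPM in immunized mice (n = 2 each), 2 of 10 neutrophil genes adjusted over the list alone. They came from Cpa3Cre/+ day 3 replicate 1 (5.41 and 8.53 CPM), while replicate 2 had 0.249 and 0.548 CPM. The neutrophil count was lower without 15 of the 23 libraries, and was 0 without Cpa3Cre/+ day 3 replicate 1, immunized replicate 1 or 2 or day 1 replicate 1 or 2 or Cpa3+/+ naive replicate 1.

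EdgeR called 0 genes on day 1 and 0 on day 3 in Cpa3Cre/+ over all genes, with 366 and 743 at an unadjusted p under 0.05, and DESeq2 called 0 and 0. The blood count was 0 without Cpa3Cre/+ immunized replicate 1 or day 1 replicate 2, and 3 without Cpa3Cre/+ immunized replicate 2, day 3 replicate 1 or 2, or Cpa3+/+ immunized replicate 2, day 3 replicate 1 or 2 or day 5 replicate 1 or 2. The Itgae call was lost without 15 of the 23 libraries, and the protease count was 0 and 1 without Cpa3Cre/+ immunized replicate 1 and day 3 replicate 2. The smooth muscle count was 0 without Cpa3Cre/+ immunized replicate 2 or day 3 replicate 1 or 2, 4 without Cpa3Cre/+ day 1 replicate 1 or 2, and 3 without Cpa3+/+ naive replicate 2, immunized replicate 1 or 2, day 1 replicate 3, day 3 replicate 1 or 2 or day 5 replicate 1 or 2.

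On day 5 in Cpa3Cre/+ mice, mast cell proteases and heat shock genes were higher than after immunization alone, and both lists lost their camera calls (adjusted p = 0.368 for both with an estimated correlation). Of 8 proteases 6 rose adjusted over the list alone and 0 over all genes, with Mcpt1 going from 4.78 ± 0.583 (n = 2) to 55.4 ± 11.7 CPM (n = 3; 3.77 ± 0.80) and Mcpt2 from 1.42 ± 0.47 to 23.5 ± 6.64 CPM (4.22 ± 0.89). Of 12 heat shock genes 10 rose, with Hspa1a at 3.03 ± 0.94, Hspa1b at 3.31 ± 1.05, Hspe1 at 1.00 ± 0.23 and Hspa8 at 1.02 ± 0.32. Hspa1a was 5.81, 16.8 and 1.51 CPM in day 5 replicates 1, 2 and 3, against 1.38 and 1.15 CPM in the immunized libraries, and Hspa1b was 12.5, 26.1 and 2.26 CPM against 1.67 and 2.14 CPM. Replicate 3, which stood apart on the first principal component, thus lay near the immunized libraries in both genes, while its Hspe1 (154 CPM) was the highest of the 5. The heat shock count was 1 with the female libraries alone and 6 with GC correction. Of 13 mitochondrially encoded genes 7 rose (adjusted p = 0.368 with an estimated correlation), with mt-Nd3 at 1.84 ± 0.43 and mt-Co3 at 1.61 ± 0.38. Mitochondrially encoded reads made up 8.31, 10.2 and 5.58% of day 5 replicates 1, 2 and 3, against 6.26 and 4.62% of the immunized libraries. Of 15 alarm genes 3 rose: the epithelial oxidase Duox2 (4.13 ± 1.40), its maturation factor Duoxa2 (3.52 ± 1.21) and Sprr2a1, at least 9.27-fold higher. Of the 15, 9 had negative values, and the list had a median of −0.25 and a mean of 0.77. The goblet cell product Retnlb was at least 40.8-fold higher, from 0 counts in immunized mice to 4.31 ± 3.47 CPM (n = 3), and Ccl8, a chemokine, changed by 3.24 ± 1.05, both among 13 type 2 genes. Spink4, a goblet cell gene, rose by 1.14 ± 0.37, with Retnlb 2 of 14 goblet cell genes. Fcer1a and Ms4a2 rose, 2 of 15 other mast cell markers, to 0.79 ± 0.0723 and 0.747 ± 0.258 CPM (n = 3) from 0.0382 ± 0.054 and 0.0364 ± 0.0515 CPM (n = 2), and Ms4a2 was 1 of 3 basophil genes.

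In the edgeR fit 6 genes fell over all genes on day 5 in Cpa3Cre/+ and 0 rose, while DESeq2 called 72 higher and 105 lower, with St3gal4, Mcpt2 and Mcpt1 among the higher. Without the 3 libraries apart on the principal components edgeR called 364 higher and 1135 lower. With the female libraries alone it called 0, and without the 3 libraries with follicle transcripts it called 0. Among the 6 were Rab43 (ENSMUSG00000030055, −3.34 ± 0.49), the pseudogene Gm10060 (ENSMUSG00000110669, −3.36 ± 0.53), the Integrator subunit Ints1 (ENSMUSG00000029547, −1.59 ± 0.25), Scaf1 (ENSMUSG00000038406, −1.37 ± 0.23) and the repressor Cic (ENSMUSG00000005442, −1.20 ± 0.20). Their edgeR adjusted p ranged from 0.0283 to 0.047. Each gene named here was also lower in the naive and day 3 Cpa3Cre/+ libraries than in the immunized ones. Rab43 stood at 0.488 and 1.01 CPM (naive), 3.79 and 3.89 (immunized), 0.694 and 0.747 (day 3) and 0.298, 0.556 and 0.282 (day 5). Ints1 stood at 30.4 and 29.4, 47.1 and 57.9, 35.8 and 27.9, and 15.8, 16 and 26.6 CPM. The fall thus holds against the immunized state, where these genes were high. The same contrast in Cpa3+/+ gave these 6 genes negative values as well, with Rab43 at −3.78 ± 0.60 and edgeR adjusted p from 0.0651 to 0.129. Their transcripts had a median GC content of 61.9%, against 49.6% over the genes tested, and with the GC correction chosen after the data were seen their median changed from −1.68 to −0.93 and 0 of the 6 passed. The genes differed in this: Rab43 stayed at −3.01 ± 0.51 (adjusted p = 0.0596) and Gm10060 at −2.35 ± 0.57, while Cic went to −0.44 ± 0.18. Of 15 B cell genes 7 fell, among them Ighd (−4.22 ± 1.32) and Cd79a (−2.15 ± 0.69; adjusted p = 0.771 with an estimated correlation for that list). Ighd stood at 27 CPM in Cpa3Cre/+ immunized replicate 2, a library with follicle transcripts, at 1.17 CPM in immunized replicate 1 and between 0.67 and 0.941 CPM on day 5. Cd79a stood at 27.5, at 13, and between 4.24 and 6.12 CPM. The B cell count was 0 without that library. Ighg2b fell (−2.87 ± 0.69, 1 of 20 plasma cell genes, adjusted p = 0.764 with an estimated correlation), and so did the sterol regulator Srebf2 (−0.79 ± 0.20, 1 of 19 cholesterol synthesis genes).

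The count of 6 among 1679 genes at an unadjusted p under 0.05 (DESeq2, 177) was 0 without Cpa3+/+ naive replicate 2, day 3 replicate 1 or 2 or Cpa3Cre/+ immunized replicate 1 or 2 or day 5 replicate 1 or 2. It was 1 without Cpa3+/+ naive replicate 3, 2 without Cpa3+/+ day 1 replicate 3, and 3 without Cpa3+/+ immunized replicate 1 or 2 or Cpa3Cre/+ day 3 replicate 1 or 2. It was 14 without the library labelled Cpa3Cre/+ naive replicate 1 and 324 without Cpa3Cre/+ day 5 replicate 3. The protease count was 3 without Cpa3Cre/+ immunized replicate 1. The counts of other mast cell markers, type 2 genes and goblet cell genes were lower without 16, 15 and 15 of the 23 libraries, and each was 0 without either Cpa3Cre/+ immunized library or day 5 replicate 2. The type 2 count was also 0 without Cpa3+/+ naive replicate 3. The basophil count was 0 without either Cpa3Cre/+ immunized library or day 5 replicate 1, the Ighg2b call was lost without day 5 replicate 1, and the Srebf2 call without either immunized library or day 5 replicate 1 or 2. The heat shock count was 1 without Cpa3Cre/+ immunized replicate 1 or day 5 replicate 2 and 6 without day 5 replicate 1, and the mitochondrial count was 0 without Cpa3Cre/+ immunized replicate 2. The B cell count was 2 without Cpa3+/+ naive replicate 2 or day 1 replicate 1. It was 0 without Cpa3+/+ naive replicate 3, day 1 replicate 2 or 3, day 3 replicate 1 or 2 or Cpa3Cre/+ immunized replicate 2, day 3 replicate 1 or 2 or day 5 replicate 1, 2 or 3. The alarm count was 1 without Cpa3+/+ naive replicate 2, immunized replicate 2, day 1 replicate 1, day 3 replicate 1 or 2 or day 5 replicate 1 or 2, without the library labelled Cpa3Cre/+ naive replicate 1, or without Cpa3Cre/+ naive replicate 2, immunized replicate 1, day 3 replicate 1 or 2 or day 5 replicate 1 or 2.

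**Figure D3:**
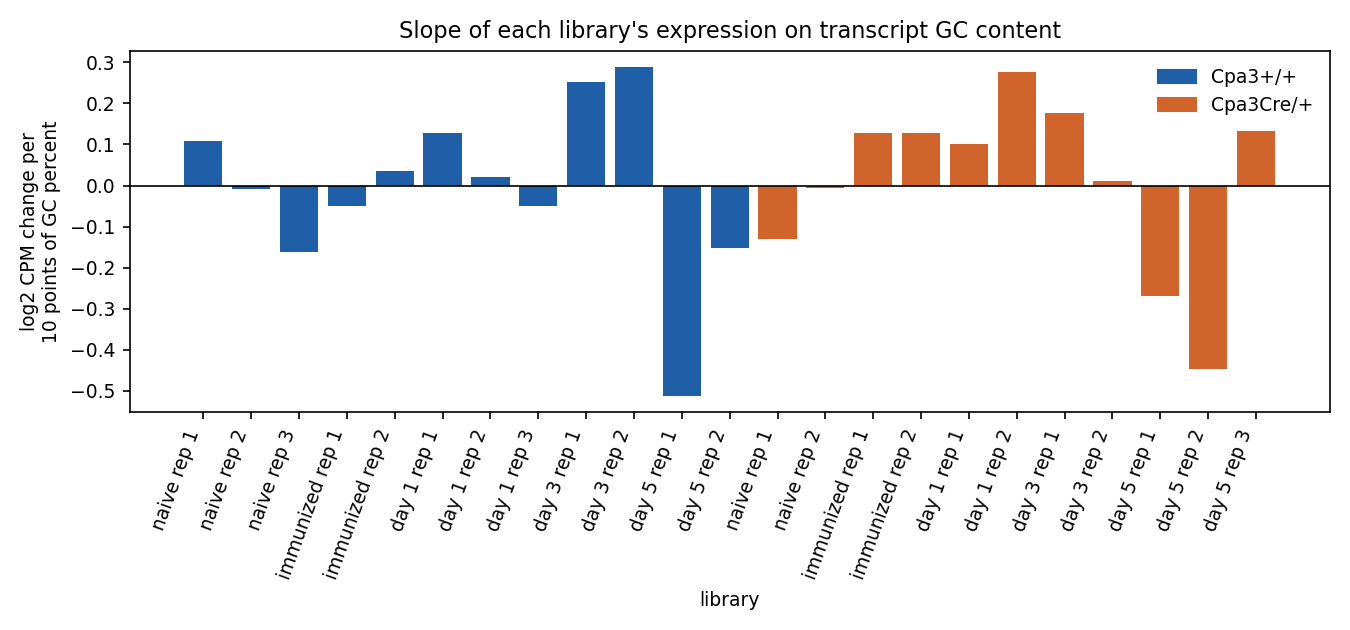
Change of log2 CPM per 10 points of transcript GC content in each library, with Cpa3+/+ in blue and Cpa3Cre/+ in orange. The slopes on day 5 were −0.512 and −0.152 in Cpa3+/+ and −0.27, −0.447 and 0.133 in Cpa3Cre/+, and the other libraries lay between −0.161 and 0.288.

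**Figure D4:**
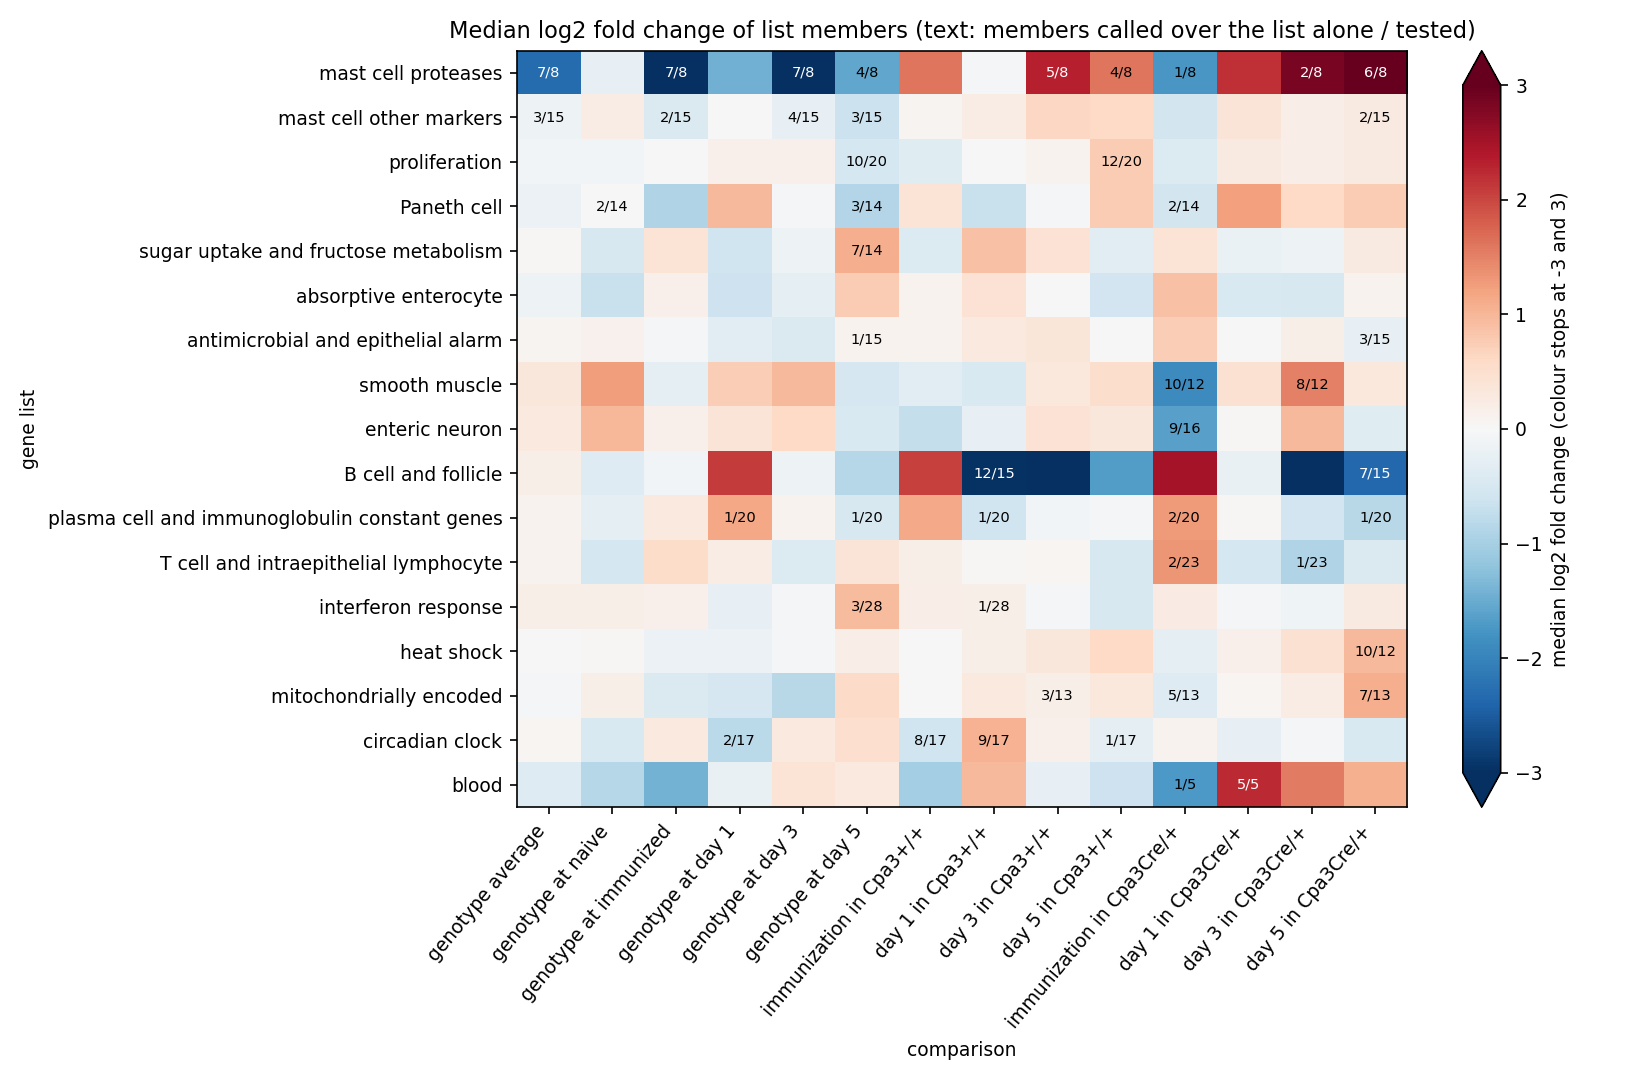
Median log2 fold change of 17 gene lists (vertical axis) in 14 comparisons (horizontal axis), with colour limits at −3 and 3; the text in a cell gives the members passing adjusted over the list alone and the members tested, and cells without text had 0 passing. Mast cell proteases fell between genotypes on day 3 with 7 of 8 members, and the proliferation list rose with 12 of 20 members on day 5 in Cpa3+/+.

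The interaction comparisons asked whether the response to challenge differed between genotypes. Clock and immunoglobulin genes gave the members that passed: Ciart (−6.28 ± 1.76) and Iglc3 (3.36 ± 0.80) on day 1, each 1 member adjusted over its list alone and 0 over all genes, and 0 members of any list passed on days 3 and 5. The clock list lost its camera call (adjusted p = 0.656 with an estimated correlation). Ciart stood at 55 CPM in Cpa3+/+ day 1 replicate 2 and at 2.85 and 4.19 CPM in the other Cpa3+/+ day 1 libraries, and its call was lost without that library and without 15 others. The Iglc3 call was lost without Cpa3+/+ immunized replicate 1, either Cpa3Cre/+ immunized library or Cpa3Cre/+ day 1 replicate 2. The mast cell proteases gave 0 members on any day. Mcpt1 went up 8.07-fold on day 3 in Cpa3+/+ and 7.35-fold in Cpa3Cre/+. On day 5 it went up 5.7-fold and 13.7-fold and Mcpt2 5.28-fold and 18.6-fold. The Cpa3+/+ folds on day 5 rested mostly on replicate 2. Mcpt1 was 59.6 and 397 CPM in day 5 replicates 1 and 2, against 26.5 and 53.7 CPM after immunization. Mcpt2 was 24 and 137 CPM, against 10.5 and 20 CPM. By camera the protease list was higher in the Cpa3Cre/+ response on days 1 and 5 (list medians 2.97 and 2.14, adjusted p = 0.00129 and 5.6e-05), and both calls were lost with an estimated correlation (adjusted p = 0.656 and 0.527). In the immunized Cpa3Cre/+ libraries Mcpt4 and Mcpt9 each stood at 0 and 0.153 CPM and Cma1 had 0 counts. These members held too few counts for a fold, so the medians are uncertain in size. Over all genes edgeR called 0 on days 1, 3 and 5, with 701, 244 and 220 at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 0. The joint test of the 3 days called 0 with edgeR, with 797 at an unadjusted p under 0.05, and 5 with DESeq2. The edgeR count was 1 without Cpa3Cre/+ naive replicate 2 or without the library labelled Cpa3Cre/+ naive replicate 1.

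Of the 44 lists, 15 had 0 members passing in any comparison: eosinophil, tuft cell, ILC2 and Th2 cell, macrophage and dendritic cell, MHC class II, eicosanoid, intestinal stem cell, absorptive enterocyte, enteroendocrine cell, fatty acid oxidation, fibroblast, endothelium, pancreas acinar cell, distal intestine position, and the chromosomal neighbours of Cpa3. The cytokine genes of type 2 immunity Il4, Il5 and Il13 had group means of at most 0.342, 0.126 and 0.367 CPM. In all, 68 of 748 pairs of a list and a comparison held a passing member, where 37.4 pairs would be counted at a rate of 0.05. Camera called 228 pairs with the preset correlation and 3 with an estimated correlation, all 3 of them mast cell proteases, lower in Cpa3Cre/+ on average, in immunized mice and on day 3.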

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

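The Cpa3 ratio tests, the test of GC content as the whole cause and the test on the library labelled Cpa3Cre/+ naive replicate 1 were written after the result was seen, and so was the choice of the patterns weighed. A pair of tests on the 6 genes lower on day 5 in Cpa3Cre/+ are given as facts only. Both left their question undecided: their median log2 fold change went from −1.68 to −0.93 with GC correction, and the difference of the library labelled Cpa3Cre/+ naive replicate 1 had a median of −0.42 over these genes.

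The response to challenge differed between the genotypes in 14, 7 and 16 lists on days 1, 3 and 5 by camera with the preset correlation, and 0 of these calls held with an estimated correlation. The 3 lists with the smallest p on each day follow, and each value is the list median of the Cpa3Cre/+ change minus the Cpa3+/+ change. On day 1 it was 1.8 for Paneth cell genes (14 of 14 positive, adjusted p = 1.02e-09, and 0.656 with an estimated correlation), −1.21 for fatty acid oxidation genes (17 of 18 negative, adjusted p = 6.62e-07, and 0.656) and 1 for macrophage and dendritic cell genes (17 of 18 positive, adjusted p = 2.64e-06, and 0.656). On day 3 it was 1.27 for smooth muscle genes (12 of 12 positive, adjusted p = 5.21e-08, and 0.911), −1.03 for T cell and intraepithelial lymphocyte genes (17 of 23 negative, adjusted p = 0.00033, and 0.911) and 2 for blood genes (5 of 5 positive, adjusted p = 0.00119, and 0.911). On day 5 it was −0.52 for proliferation genes (20 of 20 negative, adjusted p = 1.33e-09, and 0.321), 1.07 for mitochondrially encoded genes (13 of 13 positive, adjusted p = 1.33e-09, and 0.321) and 0.89 for interferon response genes (23 of 28 positive, adjusted p = 3.98e-06, and 0.603).

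Libraries were split at random within states to ask how often a grouping calls as many genes as the genotypes do. Among 100 splits 1 called as many as the 5 genes of the genotype average, which was the split by genotype itself, and the highest count of any other split was 0.

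Mast cell transcripts were left in the Cpa3Cre/+ libraries, with Mcpt1 at 55.4 CPM on day 5. Carry-over from Cpa3+/+ samples would keep the ratio of Cpa3 to Mcpt1 plus Mcpt2, and that ratio differed between genotypes (exact permutation p = 0.00117), which argues against carry-over as the whole source. The Y-linked gene Ddx3y reached 6% of the male mean in female Cpa3Cre/+ libraries, so some carry-over between libraries was not excluded. The log2 difference of the ratio was −1.1 (bootstrap interval −1.65 to −0.56). The interval holds the −1 of cells with 1 intact Cpa3 allele, so remaining mast cells may be the source. The interval resampled 2 or 3 libraries per group and is likely too narrow. Over the Cpa3+/+ libraries the ratio ran from −5.07 to −2.61 on the log2 scale, so a difference near −1 is not particular to 1 intact allele. The ratio rested on 1 to 19 Cpa3 counts per Cpa3Cre/+ library and ran from −7.27 to −3.74 on the log2 scale there, with the library labelled Cpa3Cre/+ naive replicate 1 the highest. Without that library the difference was −1.3 (−1.77 to −0.83, exact permutation p = 0.000208), with each library left out in turn it ran from −1.35 to −0.84, and with counts summed over libraries (112 and 1102 for Cpa3) it was −1.11. Mcpt8, a basophil protease, was 0.33% of Mcpt1 over the Cpa3Cre/+ libraries, which argues against basophils as the source of Mcpt1. It cannot decide the source of the remaining Fcer1a and Ms4a2, which were far scarcer than Mcpt1. Mcpt8 had 14 counts over the Cpa3Cre/+ and 11 over the Cpa3+/+ libraries.

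Proliferation genes rose on day 5 in Cpa3+/+, in libraries whose GC slopes lay below those of the immunized libraries. With GC correction the list median was 0.6 in place of 0.75, just short of the bound set for arguing against GC content, so a share of the rise could be technical. As 12 members still passed after the correction, GC content as the whole cause was argued against. Absorptive enterocyte genes had a median of −0.57 in the same comparison, and a changed share of crypt and villus in the samples was not tested.

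Sugar uptake and fructose genes were higher in Cpa3Cre/+ on day 5. With an enterocyte score as a covariate the list median was 0.49 in place of 1.09 and 1 member passed, so more absorptive epithelium in these samples and a regulation of sugar genes could not be told apart. The amounts drunk of the water with 8% sugar were not given, so a difference in intake between genotypes was not tested. With GC correction the median was 1.19 and 8 members passed, which argues against GC content as the cause.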

How the results depend on the processing

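The GC correction, the omissions of 3 libraries and the enterocyte covariate were chosen after the result was seen. Over 181 log2 fold changes of named genes under 9 settings, 1356 kept their direction and their side of the 0.05 threshold. Of the others 43 kept their direction and no longer passed, 226 kept it and newly passed, and 4 changed sign. These counts do not measure the size of a change. Most of the 181 values did not pass over all genes in the edgeR fit, so they had no call to lose. The 43 losses fell on the values that did pass. Each of the 5 genes of the genotype average lost its call under 4 of the 9 settings. Of the genes lower on day 5 in Cpa3Cre/+, Rab43 and Gm10060 lost theirs under 4, and Ints1, Cic and Scaf1 under 5. The reversed values were Defa22 between genotypes in naive mice (−0.96, females only), Cpa3 in the same comparison (0.16, females only), Cr2 on day 1 in Cpa3+/+ (2.28 without the 3 libraries with follicle transcripts), and Prkcq after immunization in Cpa3Cre/+ (0.25 without the 3 libraries apart on the principal components). The only female library of naive Cpa3Cre/+ mice was the library labelled Cpa3Cre/+ naive replicate 1, whose label Cpa3 did not check, so both values from females rest on it, and the library with the high Defa22 was left out.

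Without a filter on low counts the counts of called genes were 49 for the genotype average, 166, 77, 233, 49 and 466 for genotype in naive, immunized, day 1, day 3 and day 5 mice, 114 and 776 for immunization in Cpa3+/+ and Cpa3Cre/+, 263, 134 and 307 for days 1, 3 and 5 in Cpa3+/+, 65, 184 and 341 in Cpa3Cre/+, 202, 69 and 43 for the interactions and 728 jointly. The prior degrees of freedom were infinite in that fit and 5.5 with the filter. DESeq2 called 8 for the genotype average, 3, 7 and 15 for genotype on days 1, 3 and 5, 4 and 99 for immunization, 19, 2 and 138 for days 1, 3 and 5 in Cpa3+/+, 177 for day 5 in Cpa3Cre/+ and 5 jointly. The cause was not tested.

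With females only the counts were 0 (genotype average), 3 (genotype on day 5), 1233 (immunization in Cpa3Cre/+) and 0 (day 5 in Cpa3Cre/+). The count of 1233 set 1 library against 1, the library labelled Cpa3Cre/+ naive replicate 1 against immunized replicate 2, each assumed to vary like the other groups, and says little about the groups. With the replicate block they were 0 (genotype average) and 0 (day 5 in Cpa3Cre/+), and 1 sugar gene passed between genotypes on day 5. Of 93 pairs of libraries sharing a replicate number 18 had a correlation above 0.1, with a median of −0.01, so the numbers named no pairs. With GC correction 1 gene was called for immunization and 2 for day 5 in Cpa3Cre/+, and without the sex covariate 2 for day 5 in Cpa3+/+. Without the 3 libraries apart on the principal components the counts were 0 (genotype average), 5 and 1 (genotype in naive and day 5 mice), 888 (day 5 in Cpa3+/+), and 15 and 1499 (immunization and day 5 in Cpa3Cre/+). Without the 3 libraries with follicle transcripts they were 0 (genotype average), 1 and 0 (immunization and day 5 in Cpa3Cre/+), and 2 proliferation genes passed on day 5 in Cpa3+/+. With the enterocyte covariate 1 sugar gene passed. The cause was not tested.

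Leaving out 1 library at a time gave 0 to 6 genes for the genotype average, 0 to 1 for genotype in naive and in day 5 mice, 0 to 53 for day 5 in Cpa3+/+, 0 to 2000 for immunization and 0 to 324 for day 5 in Cpa3Cre/+, and 0 to 1 jointly. Members passing over a list alone ran from 6 to 7 for mast cell proteases (genotype average), 2 to 14 for proliferation (day 5 in Cpa3+/+) and 0 to 9 for sugar genes (genotype on day 5). Of 228 camera calls 3 held with an estimated correlation, and fry called 3. The cause was not tested.

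On simulated counts the fit recovered 2% of 2-fold and 62% of 4-fold changes for day 5 in Cpa3+/+, against 76% and 96% for the genotype average.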

Other observations

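No test in this part was chosen to explain a value; the genes were chosen after the result was seen. Cpa3+/+ day 1 replicate 2 had the highest values of several genes: Fkbp5 was 951 CPM, Zbtb16 155 CPM, Pdk4 1070 CPM, Sgk1 1870 CPM, Per1 230 CPM and Tsc22d3 342 CPM. Other genes went the opposite way, and Cpt1a (138 CPM) and Plin2 (49.5 CPM) were the lowest of all libraries there.

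In Cpa3Cre/+ day 5 replicates 1, 2 and 3 the phospholipase Pla2g4c was 1050, 969 and 112 CPM (at most 175 CPM elsewhere). The gasdermins Gsdmc2, Gsdmc3 and Gsdmc4 were 391, 515 and 60.8 CPM, 95.5, 127 and 13.5 CPM, and 376, 552 and 60.8 CPM. Duox2 was 386, 396 and 87.5 CPM, and Retnlb 5.66, 6.91 and 0.377 CPM.

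The follicle gene Cr2 reached 19.8 CPM in Cpa3+/+ immunized replicate 1. The first principal component held 25.7% of the variance, with the library labelled Cpa3Cre/+ naive replicate 1 at −105.8 and Cpa3Cre/+ day 5 replicate 3 at 71.3. The third held 11.5%, with Cpa3+/+ day 1 replicate 2 at 90.5.

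The sex labels matched Xist and Y-linked expression in 23 of 23 libraries. Ddx3y reached 4.7 CPM in female libraries, 11.4% of the male mean, and was over 1 CPM in 4 of them; in female Cpa3Cre/+ libraries it reached 6% of the male mean. Xist reached 39.4 CPM in male libraries, 8.1% of the female mean. Mitochondrially encoded reads made up 4.6 to 10.2% of a library.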
